A study of Mus musculus with 2 samples.

How the data were processed

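Gene expression and hashtag libraries of sorted mouse microglia were measured in 1 droplet pool, prepared with the 10x Genomics 3′ v3.1 chemistry and sequenced on an Illumina NovaSeq, per the labels' protocols. The authors deposited a matrix of raw UMI counts per feature and barcode, made with Cell Ranger 7.0.0 per the file headers and aligned to mm10 per the submitters' processing notes. A UMI count is the number of distinct molecular tags of a gene in a droplet, so amplification copies are counted once. The rule that chose the deposited barcodes, the gene annotation and the handling of reads shared between gene copies are not given in the sources used here. Values of members of near-identical families, such as Tuba1a, H3f3b, H2-T23 and Ifitm3, and of overlapping or antisense genes, such as Xist with Tsix, are therefore uncertain. The matrix held 32285 genes and 10 hashtags in 9975 barcodes, with 503 to 23185 gene UMIs per barcode, and 2979472 hashtag UMIs in total. The deposited feature reference gave each hashtag a name with its treatment, Oil or TAM, and a number from 1 to 5, and these names defined the groups. The oil hashtags are numbered 1 to 5 and the TAM hashtags 6 to 10 among the feature identifiers.

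Hashtags were assigned with HTODemux of Seurat 5.3.0 on centred log ratios with a positive quantile of 0.99. This gave 8097 singlets, 1695 barcodes with several hashtags (17.0%) and 183 without any (1.83%), and the last 2 kinds were left out. From the rate of mixed hashtags, about 188 doublets of the same hashtag are expected among the singlets. Scrublet, run in scanpy, called 0 of them and so has not worked here. Its median score was 0.145 in hashtag doublets and 0.115 in singlets, and no cell was removed on its account. Barcodes needed at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which 9760 of the 9975 met, and 7945 singlets were analysed. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes without sex-linked genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 (scanpy 1.11.5, igraph 0.11.9) gave 9 clusters.

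A cluster took the name of the cell type whose fixed markers had the highest median share of cells with a UMI, provided that at least 3 of them were in at least 25% of its cells and that this median was at least 50%. The limits of this rule were not fixed in advance. Cluster 5 stayed unnamed because the median of its best list, monocyte markers, was 35.8%, and cluster 6, with all 14 microglial markers and a median of 69.8%, because its median of 1508.5 UMIs was far below that of the other clusters with no microglial marker among its 10 leading genes. They held 0.667% and 4.38% of singlets. Leading genes were ranked by fold against all other cells with 1 CPM added to both. Shares rest on these rebuilt names and on the sort.

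Raw counts of microglia-like cells were summed per hashtag, and hashtags, not cells, were the replicates. Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (TMM normalization, filterByExpr on the groups, no covariate) with Benjamini-Hochberg adjustment at 0.05, over all microglia-like cells and over the largest cluster alone. Log2 fold changes are TAM over oil. Their standard error is an approximation, the absolute log2 fold divided by the square root of the F statistic. CPM values are per 1000000 UMIs after TMM scaling, except those of Xist and the Y-linked genes per hashtag and of Cdkn1a by cluster, which are per total UMIs. Gene lists fixed in advance were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the 15 lists. The fry test, which asks whether the genes of a list move one way without comparing them with other genes, gave adjusted p-values of 0.0209 for the homeostatic, immediate early and LXR lists, 0.0217 for cell cycle and 0.0264 for lysosome, and above 0.05 for the others. Of 298 list genes in 16 lists, 3 symbols were not in the feature table (Mx1, Clec7a and Lrrc33). Genes were matched by symbol only, so a gene present under another name would count as absent. Shares of clusters among singlets were compared with exact two-sided permutation tests of the difference of means over the 252 regroupings of 5 against 5, adjusted over clusters; the smallest p they can give is 0.00794. Slopes on the hashtag number from 1 to 10 were fitted with a separate mean per treatment, or per treatment and sex, with exact permutation of values within these groups; they were chosen after results were seen.

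The tests, cell filters, gene lists, cell type markers, most alternatives and the rule for named genes were fixed before the data were examined. The rule names Cx3cr1, the 10 genes each way with the smallest p among those past the threshold whose treatments did not overlap in log CPM, and up to 4 members per list with the smallest p. It leaves out Gm and Rik clones and Rpl, Rps and mt- genes. Named this way were 73 genes, of which 44 passed; 2 further genes that the rule names are not reported here, and no others took their place. A description of the cells as 1 unlabelled pool was also planned for the case that hashtag names gave no treatment, and it did not apply. Gene coordinates are from GENCODE M21, whose build GRCm38 is the mm10 of the deposited counts.

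No pair of hashtags of the same treatment differed by less than sampling noise (chi-square per gene of 1.58 to 5.31 over genes with at least 20 UMIs in a pair), so none was taken for a copy of another. Differences in tagging or handling would exceed that noise as well, so this does not show that they were separate mice. The tests were tested on simulated counts with 200 changed genes, drawn from the means and sizes of the real hashtags. For all microglia-like cells (11178 genes) 90% of 2-fold and 65% of 1.5-fold changes were recovered, with 6 false calls among 161 (3.73%). For the largest cluster (9198 genes) these values were 86%, 59% and 6 among 151 (3.97%). The simulated genes were drawn independently of each other. In the real hashtags genes shift together, with an estimated correlation of 0.674 in the immediate early list, so these rates may not carry over. No count of labelled mice, batch or date was given in the labels, and all cells shared 1 pool.

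Alternatives fixed in advance were DESeq2 1.42.0, library-size scaling, no filter on low counts, other filters on cells, another hashtag rule, all singlets in place of microglia-like cells, other Leiden resolutions, a block for the number in the hashtag name, an estimated correlation, and leaving out each hashtag in turn. Chosen after seeing the data were an HTODemux quantile of 0.95 for gene tests and shares, removal of the 5% of singlets with the highest Scrublet scores, sex, immediate early level or hashtag number as a covariate, analyses of female or male hashtags alone, and analyses without cluster 1 or without Oil1, Oil2 and Oil3. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and R 4.3.3.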

Results

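Microglia, the resident macrophages of the brain, were profiled by droplet single-cell RNA sequencing (10x Genomics 3′ chemistry) in mice carrying 1 copy of the Cx3cr1CreERT2(Litt) allele. This allele places a tamoxifen-inducible Cre recombinase under the control of Cx3cr1, the fractalkine receptor gene of microglia. The mice were 12 weeks old and had received either the oil vehicle or tamoxifen (TAM), an estrogen receptor ligand that releases CreERT2 into the nucleus, for 4 weeks. Cells positive for CD11b and CD45 and negative for Ly6G and CD206 were sorted from perfused brains, tagged with oligonucleotide-bearing antibodies (hashtags) and pooled into 1 gene expression library and 1 hashtag library. The 10 hashtags were named Oil1 to Oil5 and TAM1 to TAM5, which gave 5 replicates per treatment. The labels do not say that each hashtag was a separate mouse, so p-values here measure the spread between hashtags, which may be technical. Tamoxifen-treated mice without Cre were not analysed here.

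The matrix held 51821041 UMIs of 32285 genes in 9975 barcodes, with a median of 4974 UMIs per barcode. After assignment to hashtags and filtering, 7945 single cells remained, and 7544 of them lay in 7 clusters called microglia-like, where the median of 14 microglial markers was found in 96.6% to 100% of cells. Each hashtag contributed 585 to 909 microglia-like cells and 2964226 to 4847597 UMIs, at median depths of 4805 to 5043 UMIs per cell. No cluster was named for monocytes, neutrophils, CNS-associated macrophages, lymphocytes, neurons, glia or vascular cells. The remaining cells formed cluster 5, led by the MHC class II genes H2-Eb1, H2-Aa and H2-Ab1, and cluster 6, with a median of 1508.5 UMIs and mitochondrial transcripts among its leading genes. In cluster 6 all 14 microglial markers were detected too, with a median of 69.8% of cells. Both were left unnamed.

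Xist, the noncoding RNA of the inactive X chromosome, separated the hashtags into 6 with 1257 to 1729 UMIs per 1000000 (CPM) and 4 with 5.26 to 7.78 CPM. The summed CPM of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 1.49 to 4.11 in the first set and 334 to 353 in the second. Oil1, Oil2, TAM1 and TAM2 are therefore called male and the others female below, a reading of the data and not of the labels. Each treatment held 2 male and 3 female hashtags.

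The main comparison asked which genes differed in microglia between TAM-treated and oil-treated carriers of the allele. The cell cycle inhibitor gene Cdkn1a and 7 of 18 cell cycle genes rose with TAM, while 17 of 23 immediate early genes and 5 of 20 homeostatic genes, Cst3 among them, fell. None of these 3 lists held with an estimated correlation (adjusted p = 0.266, 0.266 and 0.350, camera). Of 11178 genes tested on counts summed per hashtag, 191 rose and 326 fell (edgeR quasi-likelihood test, adjusted p below 0.05), so that 36.9% of the 517 called genes were higher. With scaling by library size alone, 598 genes passed and 58.2% of them were higher, and all 517 genes had the same sign. The hashtags of both treatments did not overlap for 320 of the 517 genes, and for 5.23% of all tested genes against 0.794% given by chance. Without Oil2, Oil3, TAM3, TAM4 or TAM5 the count was 327, 249, 275, 268 or 251, and without Oil1, Oil2 and Oil3 together, the hashtags with the most immediate early RNA, it was 7. In that fit of 2 oil against 5 TAM hashtags all 517 genes had the same sign and the log2 folds of Cit, Cdkn1a and Lockd were 2.27, 1.67 and 3.09, close to those of all hashtags, while that of Egr1 was −2.21. All hashtags of that fit also took part in the main fit, so the shared signs are no separate support. Both oil hashtags left in it are female while TAM1 and TAM2 are male, so sex is not balanced there. The count was 80 with the level of the immediate early genes as a covariate (13 of them among the 517) and 41 with the number of the hashtag from 1 to 10 as a covariate (9 among the 517), 869 with sex as a covariate, 111 in male hashtags alone, 841 without a filter on low counts and 92 under a stricter hashtag assignment. That assignment left 1 microglia-like cell in Oil5 and 4 in Oil4 against 861 in Oil3. Calls lost under it therefore cannot be told apart from an effect of few cells.

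Cx3cr1, the locus of the knock-in (chromosome 9, positions 119901616 to 120069879 on the minus strand of GRCm38), was at 2173 ± 83.1 CPM in oil and 2041 ± 53.7 CPM in TAM hashtags (SD, n = 5 each). Its log2 fold change of −0.09 ± 0.03 (SE) did not pass the edgeR test (adjusted p = 0.152). The 3′ counts were not divided between the wild-type and the knock-in copy, so the value does not check the genotype.

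Among the genes that rose with no overlap between treatments, those with the smallest p included genes of cell division. Cit and Kif23, a kinase and a kinesin of cytokinesis, rose by 2.29 ± 0.35 and 2.85 ± 0.48 on the log2 scale. The kinetochore gene Spc25 rose by 1.77, the mitotic kinase Cdk1 by 1.75, the helicase gene Zgrf1 by 1.35 and the long noncoding RNA Lockd by 3.16. These transcripts were rare, at 0.818 to 3.06 mean CPM in oil hashtags. Tcf7l2, a transcription factor of Wnt signalling, rose by 0.29 ± 0.04 from 158 CPM, and the noncoding RNA AI480526 by 0.85 ± 0.13. Adjusted p-values of these genes lay between 0.0036 and 0.0051 (edgeR), and none passed with the immediate early level or the hashtag number as a covariate. With these covariates Tcf7l2 was at 0.32 ± 0.08 and 0.30 ± 0.09 and Zgrf1 at 1.19 ± 0.41 and 1.25 ± 0.47, so that their folds stayed of like size while the standard errors grew, and Lockd was at 1.52 ± 0.75 and 1.54 ± 0.87.

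Among the genes that fell with no overlap, Ddx3x, an RNA helicase gene on the X chromosome, had the smallest p (log2 fold −0.45 ± 0.05, adjusted p = 8.1e-04, edgeR). H3f3b, which encodes histone H3.3, fell by 0.68 ± 0.09 and the tubulin gene Tuba1a by 0.51 ± 0.07. Nsun6, an RNA methyltransferase gene, fell by 0.90, the small GTPase gene Arl4c by 0.40 and the tetraspanin gene Cd53 by 0.27. Cst3, which encodes the protease inhibitor cystatin C, fell from 38282 ± 2561 to 31541 ± 1276 CPM (log2 fold −0.28 ± 0.04, adjusted p = 0.0028, edgeR). Ddx3x and Cst3 also passed with either covariate (Ddx3x −0.48 and −0.49, Cst3 −0.34 and −0.35), whereas H3f3b, Tuba1a, Nsun6, Arl4c and Cd53 did not, Nsun6 being at −0.26 and −0.06. Cst3 did not pass in male hashtags alone (−0.12, adjusted p = 0.286, edgeR) or under the stricter hashtag assignment (−0.20, adjusted p = 0.943). Of the 44 named genes past the threshold, 37 lost their call and kept their sign with the immediate early level as a covariate. With the hashtag number 31 did so. Others changed sign and did not pass either. Only Ddx3x, Cst3, Lpl and Sparc kept their call with the level, and only Ddx3x, Cst3 and Lpl with the number. In male hashtags alone 30 lost their call, without Oil1, Oil2 and Oil3 40, and under the stricter hashtag assignment 19 of those measured there.

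**Figure D1:**
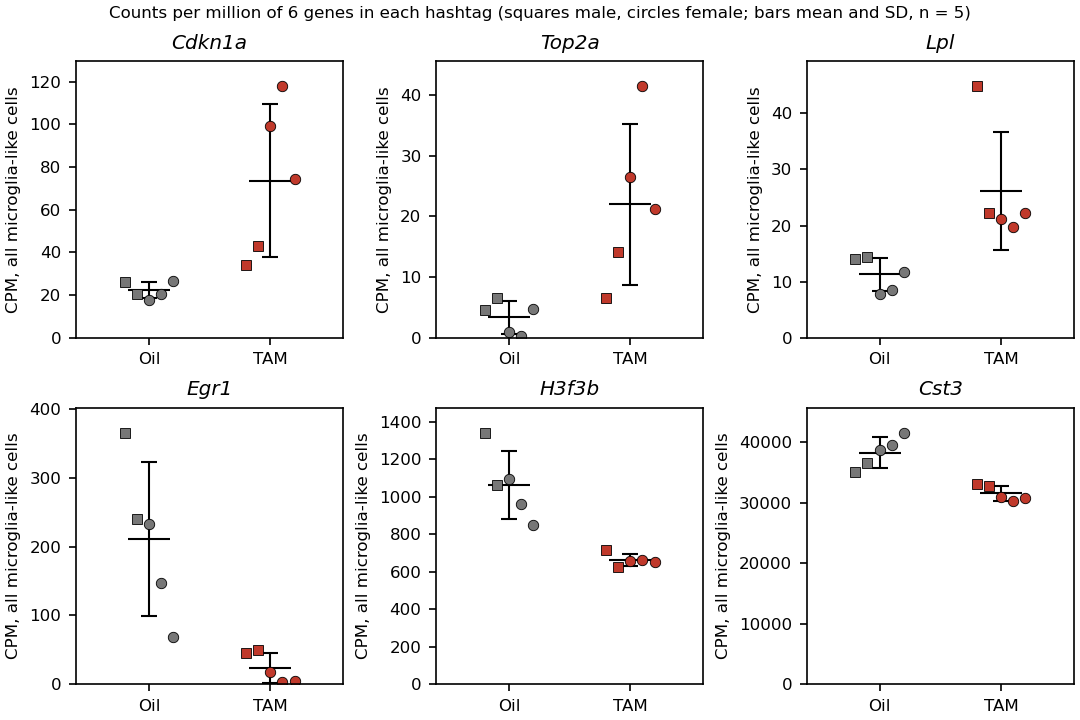
CPM of Cdkn1a, Top2a, Lpl, Egr1, H3f3b and Cst3 in each hashtag, with 5 oil and 5 TAM hashtags per panel, squares for male and circles for female hashtags, and bars for the mean and SD. Cdkn1a was at 22.4 ± 3.86 CPM in oil and 73.7 ± 35.7 in TAM hashtags, and Egr1 at 211 ± 112 and 24.0 ± 21.9.

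In the cell cycle list, 7 of 18 measured genes rose, 1 fell and 10 did not pass (11 and 1 when adjusted over the list alone), with a median log2 fold of 0.86. Top2a, the topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189, minus strand), rose from 3.40 ± 2.70 to 21.98 ± 13.2 CPM (log2 fold 2.76 ± 0.50, adjusted p = 0.0063, edgeR). Birc5, which encodes the mitotic protein survivin, rose by 2.43 ± 0.50 and Stmn1, a regulator of microtubules, by 0.97 ± 0.20. None of the 3 passed with the immediate early level or the hashtag number as a covariate, where Top2a was at 1.46 and 1.28, Birc5 at 1.23 and 0.94 and Stmn1 at 0.26 and 0.04. Stmn1 was at 0.18 in male hashtags alone (adjusted p = 0.809, edgeR), and Top2a, at 0.85, did not pass there either. Pcna, the sliding clamp of DNA replication, went the other way at −0.57 ± 0.12; it is named here after its value was seen. Of the Top2a and Mki67 UMIs of microglia-like cells, 98.0% and 97.8% lay in the dividing cells of cluster 8, which held 12 oil and 68 TAM cells; for Cdk1 and Stmn1 this was 54.8% and 40.4%. The median log2 fold of the list was 1.07 in female and 0.24 in male hashtags (adjusted p of the difference 3.3e-10, camera, and 0.0277 with an estimated correlation). The list test gave an adjusted p of 4.4e-07 (camera, preset correlation 0.01) and an adjusted p of 0.266 with an estimated correlation. The adjusted p was 0.0707 with the immediate early level and 0.180 with the hashtag number as a covariate, and 0.647 in male hashtags alone.

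In the p53 and DNA damage list, 2 of 13 measured genes rose and none fell (3 and 1 when adjusted over the list alone), with a median log2 fold of 0.18. Cdkn1a (ENSMUSG00000023067; chromosome 17, 29090976 to 29100727, plus strand), which encodes the cyclin-dependent kinase inhibitor p21, rose by 1.74 ± 0.28 on the log2 scale (adjusted p = 0.0046, edgeR). Ccng1, the p53 target that encodes cyclin G1, rose by 0.47 ± 0.08 from 23.7 ± 1.79 to 32.5 ± 2.42 CPM. The apoptosis gene Pmaip1 had a log2 fold of −0.92 ± 0.33 and did not pass (adjusted p = 0.131, edgeR). The log2 fold of Cdkn1a was 2.17 ± 0.16 in female and 0.69 ± 0.23 in male hashtags, a difference that did not pass (adjusted p = 0.0826, edgeR). Cdkn1a was at 0.61 ± 0.36 with the immediate early level and 0.59 ± 0.45 with the hashtag number as a covariate, and neither value passed. The list test gave an adjusted p of 0.0181 (camera) and an adjusted p of 0.352 with an estimated correlation, and the call was lost without TAM3 (adjusted p = 0.0719) or TAM4 (0.0642). It was also lost with the immediate early level or the hashtag number as a covariate (adjusted p = 0.758 and 0.882, camera) and in male hashtags alone (0.90015).

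Immediate early genes, which are switched on within minutes by stimuli that include tissue dissociation, fell more than any other list. Of 23 measured, 17 fell, none rose and 6 did not pass (22 fell when adjusted over the list alone), with a median log2 fold of −1.56. Egr1 (chromosome 18, 34859823 to 34864984, plus strand), a zinc finger transcription factor, fell by 3.17 ± 0.48 (adjusted p = 0.0036, edgeR), Ier2 by 2.71 ± 0.39, Zfp36, whose product degrades cytokine mRNAs, by 1.48 ± 0.24, and Ier5 by 0.94 ± 0.14. The list test gave an adjusted p of 3.5e-16 (camera) and an adjusted p of 0.266 with an estimated correlation. The mean log2 CPM of the list also differed within treatments, from 7.43 in Oil1 to 5.78 in Oil5 and from 5.72 in TAM2 to 4.46 in TAM4. With the hashtag number as a covariate the direction of the list turned to higher (adjusted p = 0.0298, camera), and Egr1 was at −0.24 ± 0.37, Ier5 at 0.0080 and Zfp36 at 0.17.

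Of the inflammatory cytokines and NF-kB targets, 3 of 19 measured genes fell and none rose (4 fell when adjusted over the list alone), with a median log2 fold of −0.21. Nfkbiz, an inducible regulator of NF-kB, fell by 1.51 ± 0.29, the cytokine genes Tnf and Il1a by 1.11 ± 0.26 and 0.51 ± 0.11 (adjusted p = 0.0074, 0.0207 and 0.0182, edgeR). The list test gave an adjusted p of 0.0084 (camera) and an adjusted p of 0.352 with an estimated correlation. The call was lost without Oil1, Oil2 and Oil3 together (adjusted p = 0.544, camera). With the hashtag number as a covariate the list turned to higher (adjusted p = 0.0376, camera), as did Nfkbiz (0.35), Tnf (0.14) and Il1a (0.17). Tnf missed the threshold without Oil3, TAM3, TAM4 or TAM5 (adjusted p = 0.0777, 0.0683, 0.0578 and 0.0657, edgeR) and Il1a without TAM3, TAM4 or TAM5 (0.0591, 0.0587 and 0.0558). Without cluster 1, which was led by immediate early genes, Il1a was at −0.19 and did not pass (adjusted p = 0.367, edgeR).

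**Figure D2:**
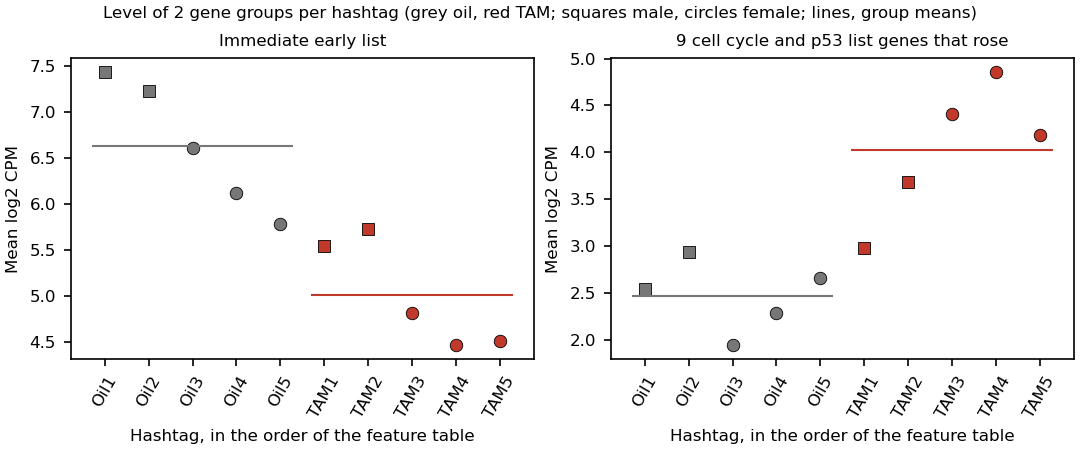
Mean log2 CPM of the immediate early list (left) and of the 9 cell cycle and p53 list genes that rose (right) in each hashtag, with hashtags on the x axis in the order of the feature table and lines at the mean of each treatment. The immediate early level was 7.43 in Oil1, 5.78 in Oil5, 5.54 in TAM1 and 4.51 in TAM5, and the level of the other genes 2.54, 2.65, 2.98 and 4.19.

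Of 20 measured genes of homeostatic microglia, 5 fell, none rose and 15 did not pass (8 fell when adjusted over the list alone). The median log2 fold was −0.07, and −0.04 with scaling by library size alone. Besides Cst3 these included Sparc, which encodes a matrix glycoprotein and fell from 3134 ± 152 to 2638 ± 86.5 CPM (log2 fold −0.25 ± 0.04), Bin1, a membrane-curvature gene (−0.18 ± 0.04), and Olfml3 (−0.20), with adjusted p-values of 0.0028 to 0.0216 (edgeR). For the whole list the adjusted p was 6.0e-04 (camera) and an adjusted p of 0.350 with an estimated correlation. Its adjusted p was 4.9e-06 with the immediate early level and 5.5e-06 with the hashtag number as a covariate, and 0.241 in male hashtags alone. Bin1 missed the threshold without Oil3 (adjusted p = 0.0569, edgeR) or TAM5 (0.0525), and without cluster 1 (−0.14, adjusted p = 0.0934).

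Disease-associated microglia genes, which are induced around amyloid plaques, moved both ways. Of 19 measured, 2 rose, 2 fell and 15 did not pass (2 and 8 when adjusted over the list alone). The median log2 fold was −0.09 (−0.06 with scaling by library size alone) and the mean 0.02, and the test direction was lower (camera adjusted p = 0.234, and an adjusted p of 0.679 with an estimated correlation). With the hashtag number as a covariate the direction of the list turned to higher and passed (adjusted p = 0.0226, camera), and with the immediate early level it was higher without passing (0.179). Lpl, which encodes lipoprotein lipase (chromosome 8, 68880491 to 68907448, plus strand), rose from 11.3 ± 2.99 to 26.1 ± 10.5 CPM (log2 fold 1.24 ± 0.24, adjusted p = 0.0076, edgeR) and was at 1.9955 and 2.26 with the immediate early level or the hashtag number as a covariate. It did not pass without cluster 1 (log2 fold 0.92, adjusted p = 0.0748, edgeR). TAM1 had 44.8 CPM of Lpl and the other TAM hashtags 19.8 to 22.3. The surface antigen gene Cd52 rose by 0.27 ± 0.07, while Trem2, a lipid-sensing receptor gene, fell by 0.20 ± 0.04 and the tetraspanin gene Cd9 by 0.18 ± 0.05. Cd52 kept its call only without Oil3 or TAM3 and Cd9 only without TAM1, with adjusted p-values over the 10 omissions of 0.0188 to 0.109 and 0.0072 to 0.118 (edgeR). Trem2 missed the threshold without TAM3 (0.0568) or TAM5 (0.0536), and Cd9 was at 0.0078 with the hashtag number as a covariate. Cd9 also missed it with scaling by library size alone (−0.14, adjusted p = 0.0947, edgeR) and Cd52 without cluster 1 (0.06, adjusted p = 0.791).

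In the lysosome list, 1 of 24 measured genes fell and none rose (8 fell when adjusted over the list alone), with a median log2 fold of −0.08, and of −0.05 with scaling by library size alone. Cd63, Ctsa and Hexa, which encode a lysosomal tetraspanin, a protease and a hexosaminidase, had log2 folds of −0.24, −0.14 and −0.17 that did not pass, although Cd63 did without TAM1 (adjusted p = 0.0041, edgeR). With sex and treatment in 1 fit, Cd63 and Hexa passed in female hashtags (−0.34 and −0.24, adjusted p = 0.0011 and 0.0108, edgeR) and Ctsa did not (0.0676). None of these 3 genes passed in male hashtags of that fit. The list test gave an adjusted p of 0.0311 (camera) and an adjusted p of 0.352 with an estimated correlation, and the call was lost without Oil3, Oil5, TAM3 or TAM4 (adjusted p = 0.0540, 0.0908, 0.0742 and 0.0841), and without Oil1, Oil2 and Oil3 together (0.0708). It was also lost with a block for the number in the hashtag name (adjusted p = 0.0622, camera), with the immediate early level or the hashtag number as a covariate (0.744 and 0.665) and in male hashtags alone (0.90015). Of the complement and phagocytic receptor genes, 1 of 19 rose and 4 fell (3 and 7 when adjusted over the list alone), with a median log2 fold of −0.07. With scaling by library size alone 1 rose and 3 fell, with a median of −0.03. C3ar1, the receptor of the C3a fragment, fell by 0.59 ± 0.13, the complement genes C1qc and C1qa by 0.14 ± 0.03 and 0.13, and Cd14, a co-receptor for lipopolysaccharide, by 0.34 ± 0.08, while the lipopolysaccharide receptor gene Tlr4 rose by 0.24 ± 0.06. The list as a whole did not pass (camera adjusted p = 0.234, and an adjusted p of 0.620 with an estimated correlation). Without TAM5 all of C3ar1 (adjusted p = 0.0521, edgeR), C1qc (0.0554) and Cd14 (0.0823) missed the threshold. So did C1qc without Oil3 or TAM4, Cd14 without Oil1, Oil2, Oil3, TAM3 or TAM4 and Tlr4 without Oil1, Oil2, Oil3, TAM3 or TAM4, with adjusted p-values up to 0.0644, 0.0895 and 0.0646 (edgeR, each without Oil3). Tlr4 was at 0.21 without cluster 1 (adjusted p = 0.0588, edgeR), and at 0.08 and 0.06 with the immediate early level or the hashtag number as a covariate. C3ar1 was at 0.08 and 0.25 and Cd14 at 0.0026 and 0.05 with the immediate early level or the hashtag number as a covariate.

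Of the type I interferon response genes, 3 of 24 measured rose and none fell (4 rose when adjusted over the list alone), with a median log2 fold of 0.13. These were Ifi27l2a (1.25 ± 0.28), the ubiquitin ligase gene Trim30a (0.24 ± 0.06) and Sp100, which encodes a nuclear body protein (0.48 ± 0.13), with adjusted p-values of 0.0182, 0.0261 and 0.0399 (edgeR). Ifitm3, an antiviral membrane protein gene, had a log2 fold of 0.62 ± 0.19 (adjusted p = 0.0673, edgeR). Of the 10 omissions of 1 hashtag it passed only without TAM1 (adjusted p = 0.0318, edgeR). With sex and treatment in 1 fit it passed in female hashtags (0.78, adjusted p = 0.0490, edgeR) and not in male ones (0.33, adjusted p = 0.747). As a set the interferon genes had an adjusted p of 0.0030 (camera), and of 0.455 with an estimated correlation. It was 0.233 without Oil5, 0.758 with the immediate early level as a covariate, and 0.996 in the opposite direction with the hashtag number as a covariate. With that covariate Ifi27l2a was at −0.03 and Trim30a at −0.02. Each of the 3 genes missed the threshold without TAM3, TAM4 or TAM5, Ifi27l2a and Trim30a also without Oil3, Trim30a and Sp100 also without Oil1 or Oil2, and Sp100 also without Oil5 or TAM2. Their highest adjusted p-values over the 10 omissions were 0.0645 for Ifi27l2a, 0.0711 for Trim30a and 0.109 for Sp100 (edgeR). Without cluster 1 they had smaller folds of 0.82, 0.14 and 0.19 and did not pass (adjusted p = 0.0724, 0.148 and 0.462, edgeR).

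Antigen presentation genes changed little. Of 14 MHC class I pathway genes, the immunoproteasome genes Psmb10 (−0.33 ± 0.06, adjusted p = 0.0089, edgeR) and Psmb8 (−0.25 ± 0.06, adjusted p = 0.0341) fell and none rose (1 rose and 3 fell when adjusted over the list alone). The median log2 fold was −0.01, the mean 0.03 and the test direction lower (camera adjusted p = 0.485, and 0.714 with an estimated correlation). None of 6 MHC class II genes passed by either adjustment, adjusted over the list alone included, and the invariant chain gene Cd74 had a log2 fold of −0.37 ± 0.19 and passed only without TAM2 (adjusted p = 0.0264, edgeR). Their median was −0.02, the mean 0.0029 and the test direction higher (adjusted p = 0.703, camera, and 0.811 with an estimated correlation). Both medians were 0.02 with scaling by library size alone. Psmb8 missed the threshold without Oil2, Oil3, TAM3, TAM4 or TAM5 (adjusted p = 0.0884, 0.0983, 0.0924, 0.0735 and 0.0867, edgeR), and with scaling by library size alone (−0.21, adjusted p = 0.0548). H2-DMa had a log2 fold of −0.06 and turned to 0.44 with the immediate early level as a covariate (adjusted p = 0.0224, edgeR).

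Lists tied to lipids and to estrogen receptor ligands gave few calls. None of 17 cholesterol synthesis genes passed, adjusted over the list alone included, with a median log2 fold of −0.14 (camera adjusted p = 0.286, and 0.455 with an estimated correlation). Hmgcs1 and Mvk, enzymes of the mevalonate pathway, had log2 folds of −0.21 ± 0.10 and −0.42 ± 0.20. Of 9 LXR targets, Mylip, a ubiquitin ligase gene of the LDL receptor, fell by 0.26 ± 0.05 (adjusted p = 0.0073, edgeR, and 0.0917 without cluster 1) and no other passed (also 1 when adjusted over the list alone). Mylip was at −0.10 and −0.06 with the immediate early level or the hashtag number as a covariate and did not pass. The median log2 fold of the LXR targets was −0.10 (camera adjusted p = 0.0549, and 0.266 with an estimated correlation) and −0.06 with scaling by library size alone, and the camera adjusted p was 0.0428 without Oil4 and 0.0353 without TAM5. Of 9 estrogen response genes, the transcriptional co-regulator Cited2 fell by 0.66 ± 0.11 (adjusted p = 0.0046, edgeR) and no other passed (also 1 when adjusted over the list alone). Cited2 was at −0.15 and −0.05 with the immediate early level or the hashtag number as a covariate and did not pass (adjusted p = 0.761 and 0.972, edgeR). Igfbp4 and Nrip1, known estrogen targets, had log2 folds of 0.34 ± 0.13 and −0.04 ± 0.04. The median of this list was 0.10 and its mean −0.0057 (camera adjusted p = 0.703, and 0.722 with an estimated correlation). None of 12 TGF-beta signalling genes passed, adjusted over the list alone included, with a median log2 fold of −0.04 (camera adjusted p = 0.485, and 0.620 with an estimated correlation) and of −0.0046 with scaling by library size alone. Smad7, an inhibitor of the pathway, was at −0.25 ± 0.08 and passed only without Oil5 (adjusted p = 0.0142, edgeR).

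**Figure D3:**
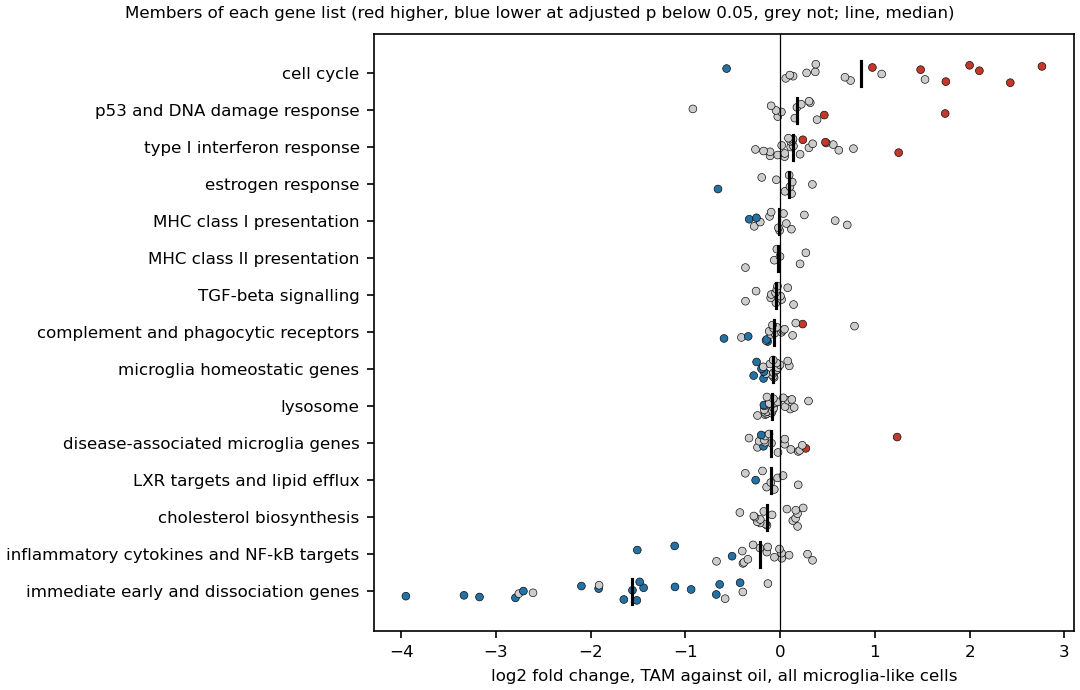
Log2 fold change, TAM against oil, of each measured member of the 15 gene lists tested in all microglia-like cells, with red for genes that rose, blue for genes that fell, grey for the rest and a black line at the median of each list. The medians run from −1.56 for immediate early genes to 0.86 for cell cycle genes.

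Over the 15 lists tested, 7 passed with the preset correlation: homeostatic, interferon, p53, cell cycle, NF-kB, immediate early and lysosome genes. None of them held with an estimated correlation. With scaling by library size alone the medians of the interferon, p53, cell cycle, NF-kB and immediate early lists were 0.17, 0.21, 0.90, −0.18 and −1.52. Of the sex-linked list only Xist was measured in the fit, at a log2 fold of 0.29 ± 1.11 across hashtags of both sexes.

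The second comparison asked which differences were present within a single cluster, since the mix of clusters differed between hashtags. The largest microglia-like cluster, cluster 2, had Cd52, Tmsb10 and H2-D1 among its 10 leading genes, and 5 mitochondrial transcripts (mt-Cytb, mt-Nd3, mt-Nd4, mt-Co1 and mt-Atp6). Its median share of mitochondrial UMIs was 1.02%, against 0.859%, 0.701% and 0.594% in clusters 0, 1 and 3. In its 2164 cells Cdkn1a rose from 19.2 ± 4.76 to 72.6 ± 40.7 CPM (SD, n = 5 each; log2 fold 2.05 ± 0.33, adjusted p = 0.0013, edgeR). Ccng1 was at 0.84 ± 0.19 and did not pass (adjusted p = 0.0643, edgeR). Egr1 fell by 2.21 ± 0.36, the AP-1 genes Jun and Junb by 1.102 ± 0.18 and 0.82 ± 0.15, Ier2 by 1.53 ± 0.27 and Cst3 by 0.19 ± 0.03. The call of Cst3 was lost with a block for the number in the hashtag name (−0.19, adjusted p = 0.0638, edgeR). The noncoding RNA C030034L19Rik rose by 3.10, the transcriptional co-repressor gene Irf2bp2, Ifitm10 and the phosphatase gene Dusp16 by 0.40, 0.30 and 0.63, and the lysozyme gene Lyz2 fell by 0.52. C030034L19Rik, Jun, Junb, Irf2bp2, Ifitm10, Dusp16 and Lyz2 are named after their values were seen.

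In this cluster 5 genes rose and 12 fell of 9198 tested (735 had an unadjusted p under 0.05). The immediate early list had a median log2 fold of −0.62, with 4 of 16 measured genes fallen (camera adjusted p = 1.1e-15), and the p53 list a median of 0.38, with 1 of 11 risen (adjusted p = 0.0013). The disease-associated list had a median of −0.13 with no member past the threshold (adjusted p = 3.0e-04), and each of these lists had an adjusted p of 0.155 with an estimated correlation. Homeostatic genes had a median of 0.03 and an adjusted p of 0.969, and the cell cycle list a median of 0.15 with none of 7 measured genes risen (adjusted p = 0.857). The interferon list had a median of −0.0028 (adjusted p = 0.775, camera). The NF-kB and lysosome lists had medians of −0.06 and −0.04 and did not pass either (adjusted p = 0.0680 each, camera). The count of genes was 10, 8, 40, 26, 10, 8 and 6 without Oil2, Oil3, TAM1, TAM2, TAM3, TAM4 and TAM5 in turn. It was 11 with DESeq2, where Egr1 did not pass (adjusted p = 0.544), 80 without a filter on low counts, where Cst3 did not pass, and 60 with sex as a covariate, and Ier2 did not pass (adjusted p = 0.0578) with a lower hashtag threshold.

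The third comparison asked whether clusters took different shares of the sorted cells. Of the 9 clusters, those whose 10 leading genes included a gene called between treatments were not compared (clusters 0, 1, 2, 4 and 8), among them cluster 1, led by Fos and Egr1, and the dividing cells of cluster 8, led by Mki67 and Top2a. Cluster 3, led by Zdhhc14, Dlc1, Cdc42bpa and Prkce, held 14.97% ± 7.68 of singlets in oil and 35.2% ± 4.59 in TAM hashtags (SD, n = 5 each; exact two-sided permutation test, adjusted p = 0.0143), and was higher in all TAM hashtags than in any oil hashtag. The share also differed within treatments, from 7.45% in Oil1 to 24.4% in Oil5 and from 29.9% in TAM2 to 39.8% in TAM4. Its slope within treatments, fitted after these values were seen, was 3.30 ± 0.855 (SE) percentage points per hashtag number (exact permutation p = 0.00903, 14400 rearrangements), where 4.05 would give the whole difference between treatments. In both treatments the hashtags numbered 1 and 2 are male and those numbered 3 to 5 female. No slope within sexes was fitted to this share, with or without cluster 1, so number and sex are not separated here. Tsix, the antisense partner of Xist, is also among the 10 leading genes of cluster 3. The MHC class II cluster 5 held 0.395% ± 0.257 and 0.951% ± 0.428 (exact permutation, adjusted p = 0.0357). Cluster 6 held 3.82% and 4.96% (exact permutation, adjusted p = 0.103), and cluster 7, led by the interferon-induced genes Ifit3, Ifit2 and Ifit1, held 1.099% and 1.99% (exact permutation, adjusted p = 0.0804), neither past the threshold.

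Shares sum to 100% within a hashtag, and cluster 1 took 33.6% ± 19.0 of oil and 2.24% ± 2.88 of TAM singlets. Among cells outside cluster 1, cluster 3 held 21.4% ± 5.51 in oil and 36.0% ± 3.94 in TAM hashtags (SD, n = 5 each; exact permutation, adjusted p = 0.0317), with a slope of 2.26 ± 0.761 (SE) per hashtag number within treatments where 2.92 would give the whole difference (exact permutation p = 0.0267). Clusters 5, 6 and 7 did not pass (adjusted p = 0.349, 0.349 and 0.619, exact permutation). The call of cluster 5 was also lost without Oil1, Oil3, Oil4, TAM1, TAM2, TAM4 or TAM5 (exact permutation, adjusted p of 0.0612 to 0.0714), and no cluster passed under the stricter hashtag assignment.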

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

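Chosen after the results were seen were the tests by sex, by the immediate early level and by the number of the hashtag, within sexes included, and the tests inside the largest cluster that bear on the cell cycle, p53 and immediate early genes; the counts over other splits of the hashtags were planned, although their bounds were written later.

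The rise of cell cycle genes with TAM differed between the sexes. The difference, tested as an interaction, had an adjusted p of 3.26e-10 (camera), and an adjusted p of 0.0277 with an estimated correlation, with median log2 folds of 1.07 in the 6 female and 0.24 in the 4 male hashtags. Stmn1 was 1.16 ± 0.20 higher in this difference (adjusted p = 0.0631, edgeR) and Cdkn1a 1.48 ± 0.29 higher (adjusted p = 0.0826, edgeR). Over all genes no interaction passed in edgeR, while 630 genes had an unadjusted p under 0.05, and no other tool was run for it. The p53 list differed as well (adjusted p = 0.00927, camera, and 0.354 with an estimated correlation, medians 0.25 in female and −0.0061 in male hashtags). The disease-associated, MHC class II and lysosome lists had an adjusted p of 0.0438 each (camera, and 0.416, 0.416 and 0.354 with an estimated correlation), with lower effects in female hashtags. Sex coincides with the numbers 1 and 2 against 3 to 5 in the hashtag names, so a difference in handling between these numbers is not separable from sex.

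Single hashtags stood apart from the other 4 of their treatment in 7 of 194 groups of values tested, where chance gives about 9.7. Oil1 had a disease-associated list level of 7.47 mean log2 CPM, the other oil hashtags 7.09 to 7.19. Oil3 had a median of 510.5 hashtag UMIs per cell, the other oil hashtags 165 to 197. TAM1 had 44.8 CPM of the lipase gene Lpl (others 19.8 to 22.3) and 46.4 CPM of the NF-kB regulator gene Nfkbiz (others 19.6 to 26.7). TAM2 had 31.8 CPM of the invariant chain gene Cd74 (others 12.7 to 18.2), TAM3 had 156.6 CPM of Cd52 (others 188 to 199), and TAM5 had a median of 0.942% mitochondrial UMIs (others 0.820 to 0.843%).

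The first pattern weighed is the rise of cell cycle and p53 list genes. A change in the mix of clusters is not enough to account for Cdkn1a, which rose by 2.05 ± 0.33 inside the largest cluster (adjusted p = 0.0013, edgeR). Ccng1, at 0.84 ± 0.19, did not pass there (adjusted p = 0.0643, edgeR). Their mean log2 fold was 1.44, each over 2 SE above 0. Both genes were picked from a pool that holds these same cells, and a mix of states within the cluster was not tested. For the cell cycle members the mix stays open, as 98.0% of Top2a UMIs lay in the dividing cells of cluster 8. Handling read by the immediate early level cannot be told apart from TAM, because within treatments the 9 called genes had a slope of −0.333 ± 0.311 (SE) per unit of that level, compatible with both 0 and the slope of −0.954 needed. The same holds for handling that follows the numbers of the hashtags, with a slope of 0.158 ± 0.124 per number against 0.310 needed. An effect of TAM, or of Cre activity after TAM, and a dependence of it on sex stay open as hypotheses, since no TAM-treated mice without Cre were analysed here.

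The second pattern weighed is the fall of immediate early genes. The mix of clusters is not enough to explain all of it, as the median log2 fold inside the largest cluster was −0.624 over the 16 genes measured there. In all microglia-like cells it was −1.56 over 23 genes, so part of the fall may go with the mix. A mix of states within the cluster was not tested. Sex is not enough either, as the median was −1.61 in the sex with the smaller change. Handling that follows the numbers of the hashtags had the values it needs: within treatments the level of the list changed by −0.387 ± 0.0516 (SE) per number (exact permutation p = 6.9e-04, 14400 rearrangements within treatments), where −0.325 per number would give the whole difference between treatments. Within treatments and sexes the slope was −0.228 ± 0.0882 (exact permutation p = 0.0694, 144 rearrangements), which does not establish a slope apart from sex. No label gives an order of handling and the numbers are names. That cells may have been handled in the order of the numbers is therefore a hypothesis. The biological alternative, a lower stimulus response after TAM, was not separable from it.

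Other splits of the 10 hashtags into 5 and 5 were drawn, 100 of the 126 with the real one included. For the count of genes in all microglia-like cells, 1 of the 100, the real split itself, gave 517, and the highest other gave 25. Because the real split is among the 100 drawn, the share cannot fall below 1 in 100. The real split also divides low from high hashtag numbers, so the count does not separate treatment from an effect that follows those numbers. For the largest cluster 2 of the 100 gave 17 or more genes, and the highest other, 35, came from Oil1, Oil2, Oil3, TAM1 and TAM2 against the rest, which holds all 4 male hashtags. For the lists 10 of the 100 gave 7 or more, the highest other being 9, so chance is not excluded for the number of lists called.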

How the results depend on the processing

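The stricter hashtag rule, DESeq2, scaling, count filters, cell filters, resolutions, the replicate block, the estimated correlation and the omission of single hashtags were planned; the fits with sex, immediate early level or hashtag number, the analyses by sex, without cluster 1 or without Oil1, Oil2 and Oil3, an HTODemux quantile of 0.95 for genes and shares, and removal of the highest Scrublet scores were chosen after seeing the data. Of the 44 named gene values past the threshold in all microglia-like cells, 30 kept their call in every alternative fixed in advance that was run for them but the stricter hashtag rule, which ended 19 calls, as did 2 of 4 named genes in the largest cluster. Of the alternatives fixed in advance, lists were rerun with the block, the estimated correlation and single omissions alone, and 4 of 7 kept their call in the first and last of these; named cluster shares were rerun with single omissions alone, where 1 of 2 kept its call.

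The count of 517 genes was 448 to 598 with DESeq2, library size, both cell filters, all singlets, the 0.95 quantile, removal of high Scrublet scores and without cluster 1, and 658 in female hashtags; 425 genes were shared with DESeq2. It was 841 without a filter on low counts, where 20098 genes were tested, 92 when 80% of hashtag UMIs had to come from 1 hashtag, 869 with sex, 80 with the immediate early level and 41 with the hashtag number as a covariate, 111 in male hashtags and 7 without the 3 hashtags with the highest immediate early level. Leaving out 1 hashtag gave 249 (without Oil3) to 665 (without TAM1), with 327, 275, 268 and 251 without Oil2, TAM3, TAM4 and TAM5. The 17 genes of the largest cluster became 11 with DESeq2, 80 without a filter and 60 with sex, and 6 (without TAM5) to 40 (without TAM1) on leaving out 1 hashtag, with 10, 8, 26, 10 and 8 without Oil2, Oil3, TAM2, TAM3 and TAM4. The stricter rule kept 1391 of 8097 singlets and as few as 5 cells in a hashtag, and it was not run for the largest cluster, where hashtags were left without cells. In the gene tests it left 1 microglia-like cell in Oil5, 4 in Oil4 and 12 in TAM2 against 861 in Oil3. Fewer cells and hashtags are part of these changes by construction; otherwise the cause was not tested.

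Against 7 lists called, 0 passed with an estimated correlation, 1 with the immediate early level, 3 in male hashtags and 5 without Oil1, Oil2 and Oil3, where the NF-kB and lysosome lists lost their call (adjusted p = 0.544 and 0.0708, camera). With the hashtag number 4 passed, which were the homeostatic list and, with their direction reversed, the NF-kB, immediate early and disease-associated lists. Against 2 cluster shares called, 1 of 3 clusters compared passed at Leiden resolution 0.3, where the clusters are others, and 0 under the stricter hashtag rule, and 1 to 3 passed on leaving out 1 hashtag (1 without Oil1, Oil3, Oil4, TAM1, TAM2, TAM4 or TAM5). Directions of called values, or of values called in the alternative, reversed as follows, and the cause was not tested. With the immediate early level Il1a was at 0.0189, C3ar1 at 0.0764 and Cd14 at 0.0026, H2-DMa at 0.44 and Xist at −7.58 (neither called without a covariate; the male hashtags had the highest immediate early levels of each treatment), and the NF-kB list pointed up (adjusted p = 0.311, camera). With the hashtag number Ier5 was at 0.0080, Ifi27l2a at −0.0281, Trim30a at −0.0207, Cd9 at 0.0078, Nfkbiz at 0.35, Il1a at 0.17, Tnf at 0.14, Zfp36 at 0.17, C3ar1 at 0.25 and Cd14 at 0.0519, and Klf2 went from −2.10 to 1.14. The interferon list then pointed down (adjusted p = 0.996, camera) and the NF-kB, immediate early and disease-associated lists up (adjusted p = 0.0376, 0.0298 and 0.0226).

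Oil and TAM hashtags share the numbers 1 to 5, but same-numbered hashtags correlated by 0.31, 0.14, 0.03, 0.11 and 0.10 in their deviations from the treatment means and 4 of 10 correlated best with their own number, so the numbers were not taken to pair them. With the replicate block 874 genes passed in all microglia-like cells and 51 in the largest cluster, and 6 lists, without the lysosome list (adjusted p = 0.0622, camera), and Cst3 in the largest cluster missed the threshold (adjusted p = 0.0638, edgeR). On simulated counts of all microglia-like cells (11178 genes) 65% of 1.5-fold changes were recovered.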

Other observations

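The gene length tests, the counts of genes called under both covariates and the values of Xist by sex and of the dividing cells were chosen after results were seen; the test of nuclear RNAs and the share test of the shortest genes inside the largest cluster had their bounds written before their values were seen.

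Xist, the RNA that coats the inactive X chromosome, was higher with TAM in female hashtags. It had 1257 to 1316 CPM in the 3 female oil hashtags and 1533 to 1729 CPM in the 3 female TAM hashtags, a log2 fold of 0.29 ± 0.05 (adjusted p = 9.6e-04, edgeR with sex and treatment in 1 fit), without overlap. Tsix, its antisense partner, is among the leading genes of cluster 3, which took a larger share of cells with TAM, and the strand setting of the counts is not given in the sources used here. Dividing cells formed 1.06% of microglia-like cells (cluster 8, led by Mki67 and Top2a). They held 26.0% of all Cdkn1a UMIs and 4.92% of all Ccng1 UMIs, so most UMIs of both p53 targets came from cells outside this cluster. Inside it Cdkn1a was at 819 ± 542 CPM in oil and 833 ± 264 CPM in TAM hashtags (SD, n = 5 each), from 12 and 68 cells in total, and in cluster 3 at 12.2 ± 5.73 and 26.7 ± 13.3 CPM. Differences were larger in cluster 0 (12.9 ± 10.5 and 85.7 ± 41.4 CPM) and cluster 2 (18.8 ± 4.67 and 72.2 ± 40.7 CPM). In cluster 1 the values were 20.2 ± 9.06 and 259 ± 454 CPM, the latter from 90 TAM cells.

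A small set of genes passed with no covariate, with the immediate early level and with the hashtag number as a covariate, 8 in all. Lpl, the receptor gene Tnfrsf11a, the cyclin gene Ccnd3, the phosphatase gene Ssh2, Rnf150 and the noncoding RNA C030034L19Rik were higher with TAM and Cst3 and Ddx3x lower in all 3 fits. Ccnd3 was at 0.32 ± 0.06 without a covariate, 0.56 ± 0.08 with the immediate early level and 0.60 ± 0.10 with the number (adjusted p = 0.0092, 0.0013 and 0.0121, edgeR), and Tnfrsf11a at 0.27 ± 0.07, 0.55 ± 0.09 and 0.56 ± 0.12 (adjusted p = 0.0476, 0.0048 and 0.0497, edgeR). Klf2, an immediate early list member, went from −2.10 ± 0.45 to 1.14 ± 0.23 with the number as a covariate (adjusted p = 0.0339, edgeR). A covariate that differs between treatments takes part of the treatment effect with it, so these fits do not show which genes respond to TAM. Lpl, a leading gene of the small cluster 4, did not pass without cluster 1 (log2 fold 0.92, adjusted p = 0.0748, edgeR).

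The third pattern weighed is gene length. In the shortest of 5 equal bins of the 11172 genes with a length (median 4505 bp), 19 genes rose and 139 fell with a median log2 fold of −0.07; in the longest bin (median 113365 bp) 61 rose and 23 fell with a median of 0.04. The shortest bin gave 26.3% ± 0.237 of UMIs in oil and 24.0% ± 0.666 in TAM hashtags (SD, n = 5 each; exact permutation, adjusted p = 0.0099), and 126 of its 139 fallen genes were outside the immediate early list. Inside the largest cluster the values were divided by their total, so their size is not comparable with those above. There the share of the shortest bin was 26.8% in oil against 26.0% in TAM hashtags (exact permutation p = 0.00794, the smallest possible). The medians of the longest and shortest bins differed there by only 0.0028, so the mix of clusters may account for the shift of typical genes and not for the whole shift of the share. On the TMM-scaled values of all microglia-like cells, handling read by the immediate early level leaves a part unexplained. Its slope within treatments was 0.566 ± 0.198 (SE) percentage points per unit where 1.39 would be needed. The slope was not fitted to shares of UMIs, where the slope needed would differ, so this does not carry over to them. For more RNA kept in the nucleus, the bound written beforehand against it was a median log2 fold that is not positive. Of 5 nuclear RNAs 2 were higher (Pvt1 0.36 ± 0.08, Firre 0.08 ± 0.09) and 3 lower (Malat1 −0.18 ± 0.03, Neat1 −0.63 ± 0.19, Kcnq1ot1 −0.04 ± 0.05). Pvt1 and Malat1 passed (adjusted p = 0.0151 and 0.0046, edgeR) in opposite directions. The median log2 fold of the 5 was −0.0378, which meets the bound against this explanation. As the few RNAs moved both ways, the question is left open here despite that bound.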
